A study of Mus musculus with 6 samples.

How the data were processed

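Messenger RNA was measured in group 1 innate lymphoid cells (ILC1) taken from the livers of C57BL/6 mice. Per the labels' protocols, the AML mice had received C1498 cells into a vein, and the healthy mice had not. C1498 is a transplantable acute myeloid leukaemia line of the same mouse strain. The cells were isolated at day 14. The labels do not say how the ILC1 were gated or sorted, whether each library came from a single animal or from a pool, or the sex of the animals. Total RNA was extracted, 2 ng of it was amplified to cDNA with a SMART-Seq kit that primes on poly(A) tails, and libraries were made from sheared cDNA. They were sequenced as single reads of 51 cycles on a HiSeq 2500. Per the labels' protocols, the libraries carry no strand information, so reads from overlapping genes on opposite strands cannot be told apart.

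The deposited files are 2 tables of the whole series. The first holds raw read counts per gene as deposited by the authors, whole numbers for 24091 gene symbols in 6 libraries, with each gene's chromosome, start, end and length in kilobases. The second is the authors' deposited table of their own comparison. Per the file headers it holds a log2 fold change, a log2 average CPM, a likelihood ratio score, a p-value and an adjusted p-value for 9769 genes, beside a value per library. The name of that table speaks of counts, yet only 0.0154% of its per-library values are whole numbers. They equal the RPKM of the deposited counts times a nearly constant factor, with a median of 1.01 in each library over genes with at least 100 counts. The authors' values per library in that table were therefore treated as RPKM and used in no test. In it 16 gene symbols had been turned into dates. The submitters' processing notes name bcl2fastq 2.18.0.12, STAR 2.6.0, HTSeq 0.6.0 and edgeR 3.28.1, and the genome builds mm10 and hg19, without saying what each was used for. The counting options, such as the treatment of reads that match several genes, are not given in the sources used here. Gene positions are printed as the count table gives them. Of its symbols, 23349 also occur in the RefSeq annotation of GRCm38.p6, which is the mm10 assembly. Of these, 99.9% lie on the same chromosome and 62.0% have the identical start counted from 1, so positions are taken as 1-based mm10.

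Groups were taken from the disease label and titles, with 3 AML and 3 healthy libraries. Column names were matched to samples by the description field. The titles number the libraries 1 to 3 within each group, and no label says that equal numbers share a day, litter or animal. No 2 libraries were alike within sampling noise. The total count per library ran from 45135093 to 51284691. At this depth a count of 3, taken as the limit that 0 reads allow in a library, equals 0.0574 to 0.0642 CPM. This limit covers counting error only, since reads without molecular identifiers are not independent molecules.

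The comparison of AML with healthy libraries used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter at its default minimum count of 10, and a design with the group only. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 12469 genes tested. The threshold was an adjusted p of 0.05. Levels are CPM on TMM-scaled library sizes, given as mean ± SD over 3 libraries, and fold changes are log2 values, AML minus healthy, with the standard error of the fit. Gene lists were tested with camera, from limma 3.58.1, at a preset inter-gene correlation of 0.01, with adjustment over the 38 lists that had at least 3 tested members. Of the 39 lists written, the list of mitochondrially encoded genes had no member in the count table. For each list, members past the threshold were also counted with p-values adjusted over the list alone. With 3 libraries per group an exact permutation test of a single gene cannot go below p = 0.1, so single genes were judged by the model fitted across all genes.

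The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named genes past the threshold by size of change, members of changed lists past that threshold, up to 2 members with the smallest p for other lists described, and 15 genes in every case (Ifng, Tnf, Gzmb, Prf1, Tbx21, Eomes, Itga1, Itga2, Klrb1c, Ncr1, Il7r, Cd200r1, Cxcr6, Ahr and Tgfbr2). As no gene passed, the first parts of the rule named none. The other genes named here were chosen after their values were seen. They are mainly the members with the smallest p of the changed lists, members counted over a list alone, and the genes with the smallest p of all. The lists of held-out myeloid, MHC class II, C1q and histone genes were also written after a first look at the data. The myeloid list was written before the values of its members were seen.

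The alternatives were other size factors, other filters on low counts, the replicate number as a block, each library left out in turn, a robust dispersion, a null fold change of 1.5, the genes of other cell types left out, DESeq2 1.42.0, limma-voom, camera with an estimated correlation, and fry. Added after seeing the data were the likelihood ratio test of edgeR, the joint omission of healthy library 1 and AML library 1, and the log2 CPM of Lyz2 as a covariate. The count test and the list test were first tested on simulated data, drawn from the means, library sizes and fitted gene dispersions of these libraries with 200 genes changed. The changed genes were drawn from those with a mean of at least 1 CPM. At an adjusted p of 0.05 the edgeR test recovered 36% of genes changed 1.5-fold, 76% of those changed 2-fold, 90% of those changed 4-fold and 94% of those changed 8-fold, each from 50 changed genes among 12256 tested. It called 13 unchanged genes, and 4 genes in a run with no gene changed. A list changed 1.5-fold was found, and 0 of 37 unchanged lists were called. Genes were drawn independently of each other, so no simulated library deviated over many genes together. The shares recovered may therefore be higher than the test can reach in these libraries. This run also cannot show how the list test behaves where genes of a list are correlated. In these libraries the estimated correlation was 0.15 for the interferon list, 0.65 for the heat shock list and 0.93 for the G2 and M phase list.

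Exons of 54 of the genes named were compared with GENCODE M21. Of these genes, 3 share at least 20% of their exonic bases with another annotated gene, so their counts are less certain. They are Ifng, Trf and Hist1h1e, which share 25.9%, 63.5% and 25.7%, each with a gene on the same strand. Members of close gene families, among them the granzymes, the Ccl3 and Ccl4 chemokines, the Ly6 genes, the H2 genes, the histones and the heat shock genes, can also share reads of this length, and their values carry that uncertainty.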

Results

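The mRNA of liver ILC1, tissue-resident lymphocytes known for producing interferon gamma, was sequenced from mice carrying C1498 leukaemia and from healthy mice. Each group had 3 libraries, called AML 1 to 3 and healthy 1 to 3. Total counts were 50366362, 51114701 and 48999439 in the healthy libraries and 47081693, 51284691 and 45135093 in the AML libraries, so depth was similar in both groups. As no label states that each library came from a separate animal, the p-values measure the spread between these libraries, which may be technical in part. The comparison asks how the transcriptome of liver ILC1 differs between leukaemic and healthy mice.

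In the AML libraries the interferon response genes were raised as a list, and so were the lists of dendritic cell genes, which hold the MHC class II genes, and of macrophage genes. Lists of immediate early genes, heat shock genes and cytotoxic granule genes were lowered. The ILC1 identity list, which holds Itga1 and Il7r, did not pass. Of 38 fixed lists tested with camera, 11 passed an adjusted p of 0.05, with 7 raised and 4 lowered. Splits of the libraries that mixed the groups passed 6 to 13 lists by the same test. None of the 11 calls held when the correlation between genes was estimated from these libraries, where the smallest adjusted p was 0.0717. By fry, which asks whether a list moves in a single direction, 3 lists passed, those of interferon response, dendritic cell and macrophage genes, each at an adjusted p of 0.0323.

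No single gene passed an adjusted p of 0.05 in the edgeR quasi-likelihood test of 12469 genes, where the smallest was 0.0764. At an unadjusted p below 0.05 there were 1102 genes, of which 634 were higher and 468 lower in AML, against 623 expected by chance. The groups did not overlap for 1937 genes, or 15.5% of those tested, where chance gives 10%. Other tools differed in their counts. DESeq2 called 149 genes, 113 higher and 36 lower, the likelihood ratio test of edgeR called 100, 76 higher and 24 lower, and limma-voom called 0. The count also rested on a pair of libraries. Without healthy 1 the quasi-likelihood test called 89 genes, without AML 1 it called 147, and without both it called 444, of which 225 were higher and 219 lower.

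**Figure D1:**
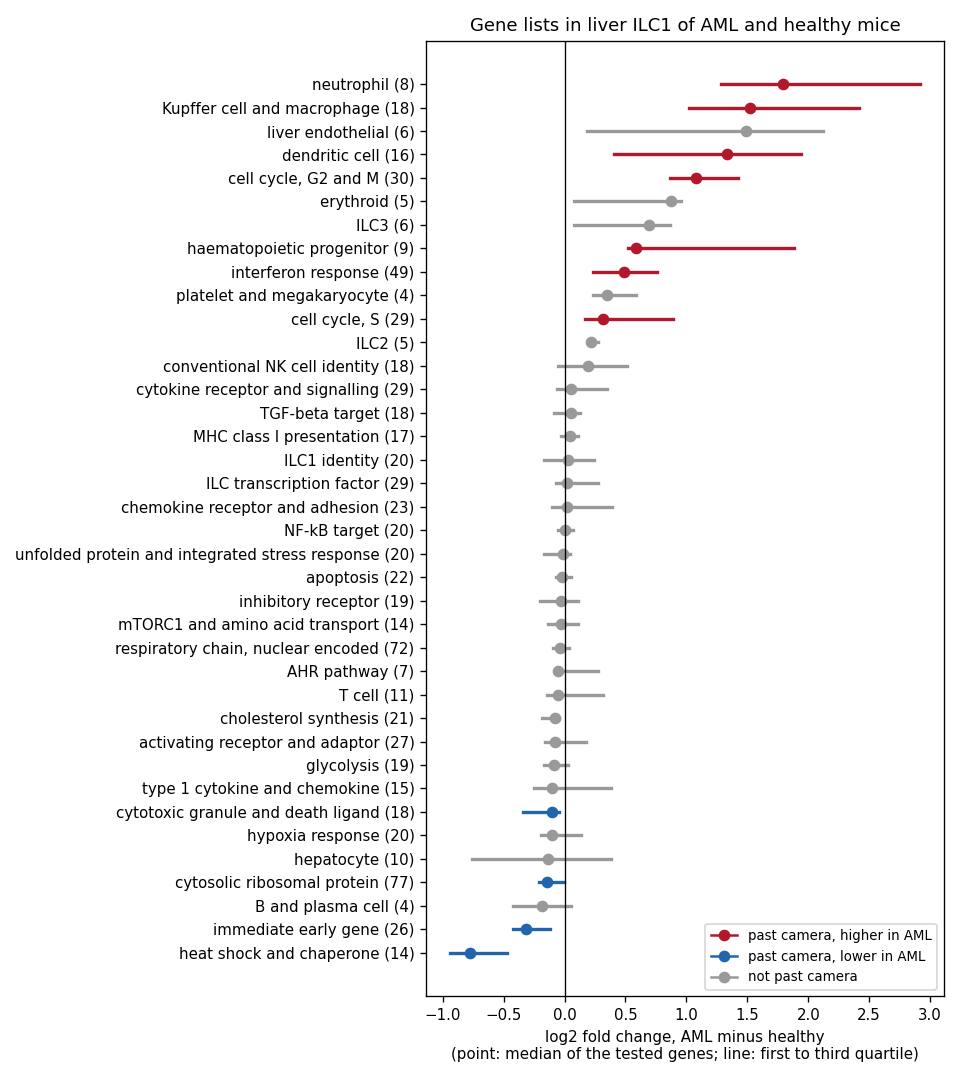
Median log2 fold change, AML minus healthy, of each of the 38 gene lists (x axis), with the number of tested genes in brackets and a line from the first to the third quartile of its genes. Red lists were raised and blue lists lowered at a camera adjusted p below 0.05 with a preset correlation. The interferon list lies at 0.49 and the heat shock list at -0.77, while the ILC1 identity list lies at 0.03.

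The interferon response list was raised. Of its 49 tested genes 48 had a positive fold change, with a median of 0.49, and 27 passed when adjusted over the list alone, all of them higher in AML, while 0 passed over all genes. The camera adjusted p was 2.84e-33, with an adjusted p of 0.0793 with an estimated correlation. Rtp4, a chaperone of receptor transport (chromosome 16, 23609919 to 23614222), measured 56.2 ± 3.86 CPM in healthy and 105 ± 10.1 CPM in AML libraries (n = 3 each), a log2 fold change of 0.91 ± 0.10 (SE) with an adjusted p of 0.122 over all genes. Dhx58, which encodes the RNA sensor LGP2, measured 27.0 ± 1.16 against 42.2 ± 2.17 CPM, and Oasl2, of the oligoadenylate synthetase family, 6.60 ± 0.339 against 14.7 ± 2.83 CPM. The interferon regulatory factors Irf9 and Irf7 had log2 fold changes of 0.51 ± 0.09 (SE) and 0.49 ± 0.11. For these 5 genes every AML library lay above every healthy library. They were chosen after their values were seen, mostly for the smallest p in the list, so this separation is no independent support. Of all genes tested 15.5% had groups that did not overlap. Members that the healthy libraries already held at 100 CPM or more moved less, with a median log2 fold change of 0.19 over 15 genes, of which 14 were positive. The interferon list kept its direction and its side of the threshold without each library in turn, with medians from 0.40 to 0.56. Over the list alone 18 members passed without healthy 2 or AML 2, 29 without healthy 3 and 17 with Lyz2 as a covariate, and without healthy 1 there were 21 higher and 1 lower.

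**Figure D2:**
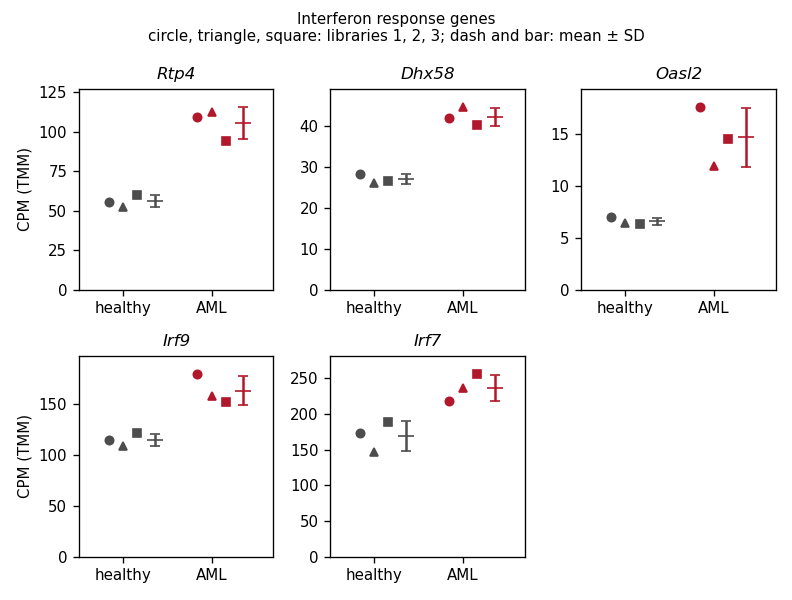
Level of 5 interferon response genes in each library, in TMM-scaled CPM on axes that start at 0, with healthy libraries in grey and AML libraries in red. Dash and bar show the mean ± SD of 3 libraries. The AML libraries lie above the healthy libraries for each gene, with Rtp4 at 105 CPM on average in AML and 56.2 CPM in healthy libraries. The genes were chosen after their values were seen.

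As a list, dendritic cell genes were raised in AML. Of 16 tested genes 15 had a positive fold change, and 8 passed when adjusted over the list alone, with 0 over all genes. The median log2 fold change was 1.33, also with Siglech set to its lower bound, and the camera adjusted p was 8.94e-20, with an adjusted p of 0.0717 with an estimated correlation. Of those 8, Cd74, H2-Aa, H2-Ab1 and H2-Eb1 belong to MHC class II, which presents antigen to CD4 T cells. Cd74, the invariant chain (chromosome 18, 60803849 to 60812652), measured 74.0 ± 27.6 CPM in healthy and 298 ± 90.1 CPM in AML libraries (n = 3 each), a log2 fold change of 2.01 ± 0.31 (SE) with an adjusted p of 0.323 over all genes. The log2 fold changes of H2-Aa, H2-Ab1 and H2-Eb1 were 1.91 ± 0.32, 1.90 ± 0.33 and 1.90 ± 0.33. Siglech, a marker of plasmacytoid dendritic cells, had 0 reads in every healthy library and 152, 42 and 124 reads in the AML libraries. With a floor of 3 counts per healthy library it was at least 36.3-fold higher in AML. Ccr9, Batf3 and Bst2 also passed over the list alone, and Bst2 is on the interferon list too. Ccr9 and Batf3 stood at 1.36 and 1.29 CPM on average in AML libraries. The rest did not pass, among them Itgax, Xcr1, Zbtb46, Flt3 and Clec9a, with log2 fold changes of -0.06, 0.15, 0.32, 1.30 and 0.46. The list median rested on single libraries, as it was 2.20 without healthy 1, 0.76 without healthy 2 and 0.91 without healthy 3. It was 0.42 over 9 genes with the stricter filter on low counts and 0.53 with Lyz2 as a covariate.

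Macrophage genes were raised as well. All 18 tested genes of the Kupffer cell and macrophage list had a positive fold change, with a median of 1.52, and 8 passed when adjusted over the list alone, against 0 over all genes. The camera adjusted p was 7.53e-19, with an adjusted p of 0.0717 with an estimated correlation. C1qb, a chain of the first complement component (chromosome 4, 136880145 to 136886177), measured 3.48 ± 0.949 CPM in healthy and 23.04 ± 14.1 CPM in AML libraries (n = 3 each), a log2 fold change of 2.73 ± 0.46 (SE) with an adjusted p of 0.323. C1qa and C1qc had log2 fold changes of 2.41 ± 0.67 and 2.71 ± 0.55, Adgre1, which encodes F4/80, 1.93 ± 0.52, and Ms4a7 2.42 ± 0.51. Left-out libraries took C1qa from 1.82 to 3.11, C1qc from 2.07 to 3.03 and Adgre1 from 1.55 to 2.71. The levels of these macrophage genes were low beside those of lymphocyte genes. Ccr2, a chemokine receptor that lymphocytes also express, was more abundant, at 199 ± 11.9 CPM in healthy and 287 ± 11.5 CPM in AML libraries. Lyz2, the lysozyme of myeloid cells, did not follow the groups, with 459 CPM in healthy 1 against 35.0 and 33.1 CPM in healthy 2 and healthy 3, and with 503, 567 and 434 CPM in the AML libraries. The median of the list was 2.36 without healthy 1, 1.13 without healthy 3 and 1.02 with Lyz2 as a covariate. Over the list alone 15 members passed without healthy 1, with the replicate number as a block and by limma-voom, 5 without healthy 2 and 4 with Lyz2 as a covariate. The neutrophil list passed too, with a positive fold change for all 8 tested genes and an adjusted p of 0.00203, or an adjusted p of 0.523 with an estimated correlation, but the call ended without AML 1, at 0.198, with the stricter filter on low counts, at 0.0523, and with Lyz2 as a covariate, at 0.425, where the alternatives ranged from 1.41e-07 to 0.523. S100a8, a calcium-binding protein of neutrophils, stood at 36.03 CPM in AML 1 and at 0.900 and 2.75 CPM in AML 2 and AML 3.

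**Figure D3:**
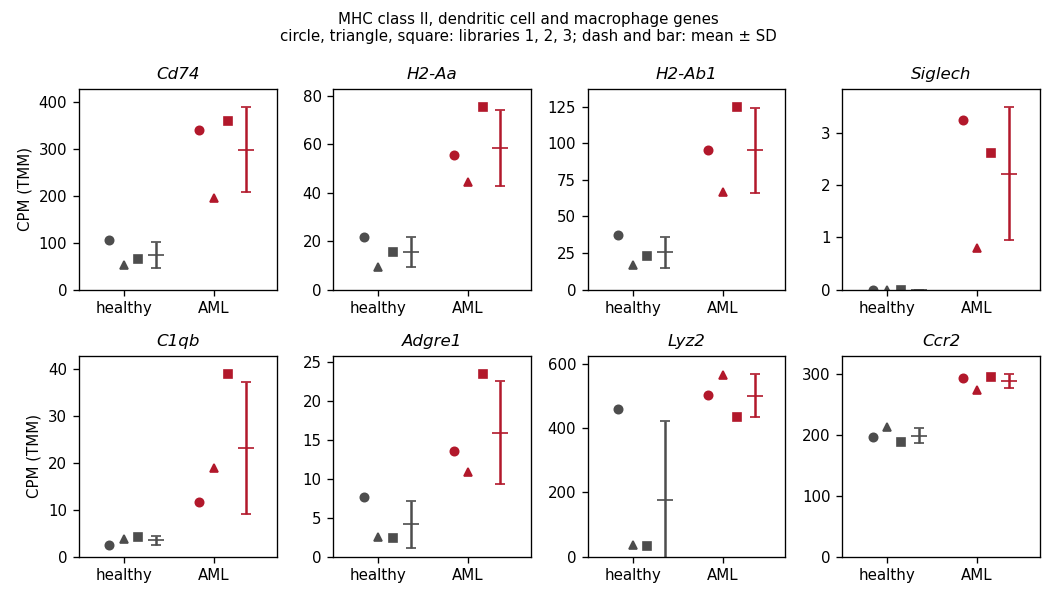
Level of 8 genes of the dendritic cell and macrophage lists in each library, in TMM-scaled CPM on axes that start at 0, where the lower SD bar of Lyz2 in healthy libraries is cut off. Dash and bar show the mean ± SD of 3 libraries. Cd74, C1qb and Siglech separate the groups, while Lyz2 in healthy 1, at 459 CPM, lies at the level of the AML libraries.

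Immediate early genes, which cells switch on within minutes of a stimulus, were lowered as a list. Of 26 tested genes 23 had a negative fold change, with a median of -0.32. Adjusted over the list alone 5 were lower, namely Dusp2, Myc, Btg2, Dusp1 and Junb, and Egr2 was higher, while 0 passed over all genes. The camera adjusted p was 7.10e-08, with an adjusted p of 0.446 with an estimated correlation. Dusp2, a phosphatase that acts on MAP kinases (chromosome 2, 127336159 to 127338377), measured 1499 ± 243 CPM in healthy and 857 ± 60.7 CPM in AML libraries (n = 3 each), a log2 fold change of -0.81 ± 0.12 (SE) with an adjusted p of 0.323. The growth regulator Myc had a log2 fold change of -0.67 ± 0.10 and Dusp1 of -0.77 ± 0.18, and Egr2, a transcription factor, of 0.49 ± 0.15. The list median was -0.51 without AML 1, where 18 members were lower over the list alone, and -0.20 without AML 3, where 4 were. The count was 2 without healthy 2, without healthy 3 or without AML 2. Its call ended with Lyz2 as a covariate, at an adjusted p of 0.161 and a median of -0.13, where the alternatives ranged from 1.25e-29 to 0.446.

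The heat shock and chaperone list was lowered, with a negative fold change for 12 of 14 genes and a median of -0.77. No member passed when adjusted over the list alone or over all genes. The camera adjusted p was 6.10e-07, with an adjusted p of 0.523 with an estimated correlation. Hsp90aa1, the stress-induced form of the chaperone HSP90, measured 272 ± 100 CPM in healthy and 147 ± 7.32 CPM in AML libraries, and Hspa8, the constitutive HSP70, 648 ± 196 against 382 ± 60.7 CPM. The healthy libraries differed widely among themselves for this list. Its median was -0.35 without healthy 1, with 0 members past over the list alone, and -0.99 without healthy 2, with 10 members. Over the list alone 9 members were lower without AML 1, 7 with the replicate number as a block and 6 by DESeq2. The list of cytosolic ribosomal protein genes also passed in the lower direction, by a small amount. The median was -0.14 over 77 genes, 58 of them negative, at an adjusted p of 2.47e-05, or an adjusted p of 0.544 with an estimated correlation, and the call ended without both healthy 1 and AML 1, at 0.101, where the alternatives ranged from 8.64e-09 to 0.544.

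Cytotoxic granule and death ligand genes were lowered slightly as a list, with a negative fold change for 17 of 18 genes and a median of -0.10. No member passed when adjusted over the list alone or over all genes. The camera adjusted p was 0.00133, with an adjusted p of 0.446 with an estimated correlation. Gzmb, the protease granzyme B (chromosome 14, 56258858 to 56262260), measured 7740 ± 599 CPM in healthy and 5865 ± 834 CPM in AML libraries (n = 3 each), a log2 fold change of -0.40 ± 0.11 (SE) with an adjusted p of 0.404. Gzma, granzyme A, had a log2 fold change of -0.36 ± 0.10 and Prf1, the pore-forming perforin, of -0.23 ± 0.08. For all 3 genes every AML library lay below every healthy library. The list median was -0.19 without AML 1, where 4 members passed over the list alone, and -0.05 without AML 3.

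Cytokine genes did not pass as a list with all libraries. Among 15 type 1 cytokine and chemokine genes the median log2 fold change was -0.10, the mean 0.26, and the camera adjusted p 0.944 in the upward direction. The list was lowered without healthy 1, at an adjusted p of 0.0460, and raised with Lyz2 as a covariate, at 0.00429. Adjusted over the list alone 4 passed, with Ccl1 and Lta higher and Ccl3 and Ccl4 lower in AML, against 0 over all genes. Ccl1, a chemokine that binds CCR8 (chromosome 11, 82176666 to 82179812), measured 5.19 ± 1.11 CPM in healthy and 16.2 ± 3.79 CPM in AML libraries (n = 3 each), a log2 fold change of 1.65 ± 0.25 (SE) with an adjusted p of 0.323. The counts over the list alone rested on single libraries, with 1 higher and 4 lower without healthy 1, 2 higher and 0 lower without healthy 3, and 1 higher and 0 lower without healthy 2, AML 2 or AML 3 and with a robust dispersion. Lta, which encodes lymphotoxin alpha, had a log2 fold change of 0.80 ± 0.25. The chemokine genes Ccl4 and Ccl3 were abundant, at 3499 ± 922 against 1864 ± 560 CPM and at 950 ± 285 against 578 ± 58.5 CPM. Ifng, the gene of interferon gamma (chromosome 10, 118441046 to 118445894), measured 822 ± 170 CPM in healthy and 672 ± 109 CPM in AML libraries, a log2 fold change of -0.29 ± 0.17 that did not pass, at an adjusted p of 0.630. Without healthy 1 and AML 1 its log2 fold change was -0.56 with an adjusted p of 0.0378, where the alternatives ranged from 0.0378 to 0.873. Tnf, at 50.9 ± 23.4 against 44.0 ± 1.42 CPM, differed by less than the spread between healthy libraries.

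**Figure D4:**
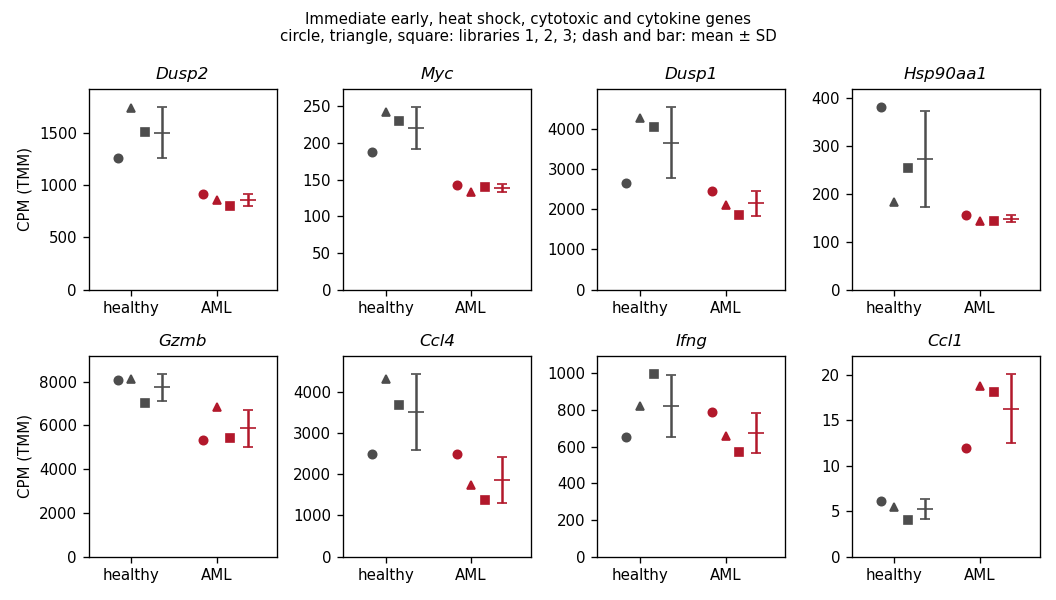
Level of 8 immediate early, heat shock, cytotoxic and cytokine genes in each library, in TMM-scaled CPM on axes that start at 0. Dash and bar show the mean ± SD of 3 libraries, with healthy libraries in grey and AML libraries in red. Dusp2, Myc and Gzmb are lower in each AML library than in each healthy library, Ccl1 is higher, and the groups overlap for Ifng, with means of 822 CPM in healthy and 672 CPM in AML libraries.

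Marker genes of ILC1 and of NK cells did not pass as lists with all libraries. The ILC1 identity list had a median log2 fold change of 0.03 over 20 genes and an adjusted p of 0.814 in the downward direction, and the conventional NK cell identity list a median of 0.19 over 18 genes and an adjusted p of 0.239. Both gained a call when libraries were left out. The NK cell list was raised without healthy 1 and without AML 3, at 0.0106 and 0.0246, and the ILC1 list was lowered without both healthy 1 and AML 1, at 0.00964. Tbx21, the transcription factor T-bet, measured 697 ± 61.3 CPM in healthy and 779 ± 39.6 CPM in AML libraries. Itga1, which encodes the liver residency marker CD49a, measured 378 ± 20.3 against 417 ± 41.3 CPM. Eomes and Itga2, which mark conventional NK cells, stood far lower, at 7.62 ± 2.61 against 11.1 ± 5.62 CPM and at 10.1 ± 1.30 against 10.4 ± 0.829 CPM. Klrb1c, which encodes NK1.1, measured 1626 ± 119 against 1450 ± 172 CPM, and Ncr1, the receptor NKp46, 1494 ± 50.7 against 1714 ± 136 CPM. The log2 fold changes of Il7r, Cd200r1 and Cxcr6 were 0.07 ± 0.20, 0.23 ± 0.12 and -0.32 ± 0.10, and that of Cd3g was -0.37 ± 0.13. Among NK cell genes the smallest p belonged to Ly6c2 and Zeb2, with log2 fold changes of 0.73 ± 0.23 and 1.55 ± 0.54. Ly6c2 is also on the macrophage list, where it passed over that list alone. Zeb2 stood at 8.83 CPM in healthy 1 against 3.32 and 1.95 CPM in healthy 2 and healthy 3. Left-out libraries took Zeb2 from 1.17 to 2.38, and its lowest adjusted p among the alternatives was 0.0158. None of these genes passed over all genes in the main test, and no member of the identity lists passed when adjusted over its identity list alone.

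Genes of the aryl hydrocarbon receptor and of TGF-beta signalling were also measured, as both act on innate lymphoid cells. Ahr had a log2 fold change of -0.05 ± 0.14 and Tgfbr2 of -0.12 ± 0.07, and neither passed. The AHR pathway list had 7 tested genes with a median of -0.05, a mean of 0.09 and an adjusted p of 0.944 in the downward direction. The TGF-beta target list had a median of 0.05 over 18 genes and an adjusted p of 0.851 in the downward direction. It was lowered without AML 1, with a median of -0.07 and an adjusted p of 0.0110, and without both healthy 1 and AML 1, with a median of -0.09 and an adjusted p of 0.0319.

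The remaining changed lists were those of the cell cycle and of haematopoietic progenitors. The list of G2 and M phase genes had a positive fold change for all 30 genes and a median of 1.08, at an adjusted p of 2.54e-06, or an adjusted p of 0.675 with an estimated correlation. No member passed over all genes or when adjusted over the list alone. Mean log2 CPM of these genes was 4.38 in AML 1, 2.23 and 2.67 in AML 2 and AML 3, 3.31 in healthy 2, and 1.16 and 1.48 in healthy 1 and healthy 3. Without healthy 2 the median was 2.21, and 21 members passed over the list alone. Without AML 1 the median was 0.07 and the call ended, at an adjusted p of 0.351. Without both healthy 1 and AML 1 the direction turned, with a median of -0.24, 8 of 30 genes positive and an adjusted p of 0.689, where the alternatives ranged from 1.50e-23 to 0.689. The S phase list, with a median of 0.31 over 29 genes and an adjusted p of 6.78e-04, or 0.712 as an adjusted p with an estimated correlation, lost its call without healthy 1, without healthy 3, without AML 1 or without both healthy 1 and AML 1, at 0.10, 0.0902, 0.790 and 0.716, where the alternatives ranged from 8.82e-13 to 0.790. The haematopoietic progenitor list, with a median of 0.59 over 9 genes and an adjusted p of 0.00408, or an adjusted p of 0.356 with an estimated correlation, lost it without AML 1, at 0.0961, and with Lyz2 as a covariate, at 0.118, and was not tested with the stricter filter, where the alternatives ranged from 8.13e-04 to 0.356. Neither of these lists had a member past the threshold when adjusted over the list alone.

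The other lists did not pass with all libraries. Of other cell types, the camera adjusted p was 0.0553 for liver endothelial genes, 0.0958 for ILC3, 0.209 for T cell, 0.211 for erythroid, 0.314 for platelet, 0.319 for hepatocyte, 0.493 for ILC2 and 0.650 for B and plasma cell genes. In the hepatocyte list Trf, the gene of transferrin, was lower when adjusted over the list alone, with a log2 fold change of -0.38 ± 0.09. Of receptors and regulators, it was 0.306 for inhibitory receptors, 0.354 for cytokine receptors, 0.362 for ILC transcription factors, 0.444 for activating receptors and 0.814 for chemokine receptors and adhesion, where Ccr2 passed over the list alone. Among metabolic and stress lists, cholesterol synthesis stood at 0.0669, the nuclear-encoded respiratory chain at 0.186, glycolysis at 0.361, hypoxia at 0.361, mTORC1 and amino acid transport at 0.362, apoptosis at 0.388 and the unfolded protein response at 0.388. MHC class I presentation stood at 0.413 and NF-kB targets at 0.815. Some of these lists passed under alternatives. Raised were erythroid genes, at adjusted p from 5.24e-07 to 0.0217, liver endothelial genes, from 0.00103 to 0.0333, and ILC3 genes, from 0.0174 to 0.0360. Lowered were cholesterol synthesis, from 8.03e-04 to 0.0321, the respiratory chain, from 0.00205 to 0.00570, NF-kB targets, from 0.00897 to 0.0212, and mTORC1, at 0.0414. ILC transcription factors were lowered without both healthy 1 and AML 1, at 0.0240, and raised with Lyz2 as a covariate, at 0.00570. The median, the mean and the test differed in sign for inhibitory receptors, activating receptors, glycolysis, the unfolded protein response, ILC1 identity, AHR pathway, TGF-beta targets and type 1 cytokines.

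The gene with the smallest p was Camk2b, which encodes a subunit of a calcium-dependent kinase (chromosome 11, 5969666 to 6065748). It measured 24.4 ± 2.17 CPM in healthy and 61.6 ± 8.23 CPM in AML libraries (n = 3 each), a log2 fold change of 1.34 ± 0.12 (SE) with an adjusted p of 0.0764. Among the genes with the smallest p was also Hist1h1c, a linker histone, at 57.2 ± 15.8 against 23.7 ± 2.32 CPM and a log2 fold change of -1.27 ± 0.20 with an adjusted p of 0.323. The authors' deposited table, which holds a likelihood ratio statistic, lists 74 genes with an adjusted p below 0.05 and marks 38 as up and 23 as down. All 74 had the same sign in the quasi-likelihood fit and an unadjusted p below 0.05 there. Fold changes of both sources correlated at 0.999996 across genes, as both rest on the same libraries, so equal signs are no independent support. In the authors' deposited table the log2 fold changes were 1.34 for Camk2b, 2.02 for Cd74, 0.91 for Rtp4 and -0.80 for Dusp2. The adjusted p values differed. By the authors' likelihood ratio test they were 6.51e-15, 1.45e-11, 7.13e-10 and 1.14e-05, and by the quasi-likelihood test 0.0764, 0.323, 0.122 and 0.323.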

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

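The likelihood ratio test of edgeR, the joint omission of healthy 1 and AML 1, and Lyz2 as a covariate were chosen after seeing the data. For the number of genes past the threshold, 0 by the quasi-likelihood test, the count was 1 with upper-quartile factors, 2 with no filter on low counts and 1 with the stricter filter of 5 CPM in 3 libraries. It was 100 by the likelihood ratio test of edgeR and 149 by DESeq2, 0 by limma-voom, with a robust dispersion, with the size factors of DESeq2, with genes of other cell types left out, against a fold of 1.5 and with Lyz2 as a covariate. Leaving out each library in turn gave 0 to 147 genes, with 89 without healthy 1 and 147 without AML 1, and leaving out both gave 444. The cause was not tested for any of these differences.

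For the number of gene lists past the threshold, 11 by camera with a preset correlation, the count was 0 with an estimated correlation and 3 by fry. The cause was not tested. Leaving out each library gave 11 to 15 lists, and of the 11 lists 7 were kept in the same direction without AML 1 and at least 10 without each other library. With other size factors all 11 were kept. The robust dispersion does not enter the list test, so its list calls equal the main ones by construction and are no check.

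The replicate number as a block left 0 genes past the threshold, at a smallest adjusted p of 0.118, and 11 lists, all 11 of them the same. Deviations from the group means correlated at 0.13, -0.05 and 0.16 for libraries with equal numbers, and healthy 2 correlated best with AML 1, so the numbers are not taken to pair the libraries.

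Of 54 named genes under the alternatives counted here, 710 values kept direction and side of the threshold and 88 passed the threshold in the same direction. Another 9 turned direction, none of them past the threshold there. Left out of these counts were the likelihood ratio test, the raised null fold change, the run without genes of other cell types, and Lyz2 as a covariate. How many named genes turned direction with Lyz2 as a covariate was not counted. Left-out libraries took Tnf from -0.53 to 0.12, Itga2 from -0.058 to 0.13, Il7r from -0.14 to 0.24 and Ahr from -0.18 to 0.030. Without both healthy 1 and AML 1, Eomes stood at -0.14 and Il7r at -0.019. The cause was not tested. The median log2 fold change of all genes was 0.01 with TMM, 0.0084 with the size factors of DESeq2 and 0.03 with upper-quartile factors. The other deposited table holds RPKM, so the planned run on it was not made. At the depth of these libraries a count of 3 equals 0.0574 to 0.0642 CPM, and lower levels are not measured.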

Other observations

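Of the tests below, the ratio of interferon excesses, the overlap of libraries for the heat shock and immediate early genes and the bound on S phase genes were chosen after the result was seen, as were the lists of MHC class II, C1q and histone genes. The held-out myeloid list and Lyz2 as a covariate were also chosen after a first look at the data, but before the values they gave.

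Genes of MHC class II, written as a list of its own, were higher in AML for all 8 tested members, with a median log2 fold change of 1.78, and 7 of them passed when adjusted over the list alone. Among linker and core histone genes of the replication-dependent clusters most fold changes were negative. Of 37 tested 33 had a negative fold change, with a median of -0.75, and 3 passed when adjusted over the list alone, all of them linker histones, while the directional fry p of the list was 0.143. Hist1h1c fell from 57.2 ± 15.8 to 23.7 ± 2.32 CPM, Hist1h1d from 14.4 ± 5.99 to 3.85 ± 2.03 CPM and Hist1h1e from 29.8 ± 11.5 to 9.36 ± 2.28 CPM (SD, n = 3 each). Most such transcripts lack poly(A) tails, so these libraries hold a part of them only. Fewer cells in S phase may be a candidate explanation, and the S phase list does not settle it. The AML minus healthy difference of its mean log2 CPM was 0.49, with a 95% interval from -0.69 to 1.67. The lower bound lies just above the median of the histone genes, and the interval is too wide to decide. The difference also rested on AML 1. The mean log2 CPM of S phase genes was 5.19 in AML 1 and 4.24 and 4.22 in AML 2 and AML 3. In healthy 1 to 3 it was 3.82, 4.62 and 3.75.

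Across genes, which are not independent replicates, the log2 CPM of healthy 1 correlated at 0.980 with AML 2, at 0.972 with AML 1, at 0.966 with healthy 3 and at 0.965 with both healthy 2 and AML 3. The spread of counts beyond Poisson noise put it in another order, at 71.7 for healthy 2, 73.4 for healthy 3, 74.6 for AML 1, 116 for AML 2 and 148 for AML 3. AML 1 stood apart from the other AML libraries, among others in its G2 and M phase genes and in S100a8. By the same spread it lay at 69.0, 74.6 and 84.6 from healthy 2, healthy 1 and healthy 3, and at 103 and 121 from AML 2 and AML 3. By correlation AML 1 was closest to AML 2, at 0.975, then to healthy 1, at 0.972, and AML 3, at 0.963. With healthy 2 and healthy 3 the values were 0.957 and 0.951. The labels give no day or batch that separates these libraries.

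Macrophage and MHC class II genes were higher in the AML libraries, and more myeloid cells in them is a candidate explanation. It named in advance that myeloid genes on no other list would rise, and their median log2 fold change was 1.42, with 33 of 34 positive, though 0 passed when adjusted over the list alone, 12 of them stood at 10 CPM or more in healthy libraries, 31 were higher in healthy 1 than in the other healthy libraries, 17 had a healthy SD above the healthy mean, and the directional fry p was 0.0643. With Lyz2 as a covariate, the median was 3.92 for the C1q genes against 2.71 without it, at a fry p of 0.0545, and 1.41 for MHC class II against 1.78, at a fry p of 0.107, so that myeloid cells expressing Lyz2 stay open as a source by these tests. The libraries do not show C1q following Lyz2, as healthy 1 held 459 CPM of Lyz2 but 4.25 CPM of C1q transcripts, the lowest of all, and AML 1 to 3 held 503, 567 and 434 CPM of Lyz2 with 28.3, 40.6 and 89.0 CPM of C1q. As no gate is stated, transcripts of other cells cannot be told apart from a change within ILC1 for these genes, and an effect of leukaemia on either stays untested.

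Interferon response genes were higher in the AML libraries. With Lyz2 as a covariate their median log2 fold change was 0.58 against 0.49 without it, at a fry p of 0.0154. Of the healthy libraries only healthy 1 held Lyz2 at the level of the AML libraries, so this fit rests mainly on healthy 1. There the interferon median lay at -0.08 on the log2 scale over the healthy mean, against 0.48, 0.47 and 0.36 in AML 1 to 3. Resting on a single library, the test cannot by itself argue against myeloid cells that express Lyz2. The cells behind the C1q signal stay open, by a test that was rewritten after a first test of the same explanation, on members at 100 CPM or more in healthy libraries with a median log2 fold change of 0.19, had been seen and found unable to argue against it. AML 3 held 3.14 times the C1q transcripts of AML 1, yet its interferon excess over the healthy libraries was 0.73 times that of AML 1, with an upper bound of 2.10. A response of ILC1 themselves in leukaemic mice stays open too. It was not separated from the cells behind the C1q signal or from myeloid cells that express Lyz2.

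As lists, heat shock and immediate early genes were lower in the AML libraries by camera at the preset correlation. Neither call held by camera with an estimated correlation, at adjusted p of 0.523 and 0.446. Handling stress that varied from library to library was tested for each list by itself, and the libraries of the groups overlapped for both. The lowest healthy minus the highest AML library was -0.58 on the log2 scale for heat shock genes, where the widest group spanned 1.33. It was -0.14 for immediate early genes, with a span of 0.61. For heat shock genes only healthy 2, at 6.26, lay below any AML library. For immediate early genes only AML 1, at 8.24, lay above any healthy library, with AML 2 and AML 3 at 7.78 and 7.63. The test used no record of handling, and noise can give such an overlap. It therefore cannot decide, and handling stays open for either list. A cause shared by both lists was not shown, as the mean log2 CPM in healthy 1, 2 and 3 was 7.58, 6.26 and 7.08 for heat shock genes and 8.11, 8.30 and 8.34 for immediate early genes, with healthy 1 highest for the one and lowest for the other. A lower activity of ILC1 in leukaemic mice stays open and was not tested.

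The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05, so the splits cannot settle whether chance is excluded. The real split gave 0 genes past the threshold, and the highest of the others 1, so that all 10 splits gave as many. At an unadjusted p below 0.05 it gave 1102 genes and the highest other 1718, with 2 of the 10 splits as high, the other of which set healthy 1, healthy 2 and AML 1 against the rest. It gave 11 gene lists and the highest other 13, with 5 of the 10 splits as high. The other splits, which all mixed the groups, gave 6 to 13 lists. The count of 11 lists therefore does not set the real split apart.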
